A study of Homo sapiens with 8 samples.

How the data were processed

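The samples were 8 libraries of labelled RNA from U2OS, a human osteosarcoma cell line. Per the labels' protocols, the RNA carried 4-thiouridine (4-SU), a base analogue that cells build into RNA made while it is present, and was taken up in Trizol before library preparation with a commercial RNA-seq kit. The assay is TT-seq, which reads newly made RNA. The labels give 4 groups of 2 libraries each, named WT, Zab, MYC and MYC_Zab, and a replicate number in each title. The labels do not state the construct behind Zab. As background, Zαβ is the usual name of the paired Z-nucleic-acid-binding domains of the RNA-editing enzyme ADAR. No label says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

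The submitters' processing notes name Trim Galore 0.6.6, STAR, SAMtools 1.11 and bedtools 2.29.2, without roles or order, and the human build hg19 and the fly build dm6. The authors then counted reads over exons of hg19 RefSeq coding genes with HOMER's analyzeRepeats program on the opposite strand, per the file headers, keeping 1 transcript per gene symbol. The command in the headers asks for raw tag counts, and a directory name in it holds words for STAR, duplicates and a spike-in. The transcript kept was chosen in each library separately, and it was the same in all 8 libraries for 10453 of the 19414 genes. Every file lists 19414 coding gene symbols, with no mitochondrial, fly or non-coding features, and no blank or summary lines.

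The deposited values are a signal rather than whole counts: per the file headers they are raw tags, yet they are not whole numbers. Within a library each value was a whole multiple of one step, between 0.204 and 0.259, so dividing by the step recovered whole reads. Between 99.96% and 100% of the values in a library came out whole within 0.02 reads. The deposited values are therefore reads times a factor per library, whose basis is not given in the sources used here. Totals in the headers end in a fraction, so a recovered read may be part of a tag, as when mates of a pair are counted apart. Of the values from 1 to 20 reads, between 77.2% and 82.7% per library were even, so reads mostly came in twos. Libraries held between 1839960 and 4072059 recovered reads.

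The design written before the data were examined assumed counts and edgeR's quasi-likelihood test. Since the unit was a scaled signal, the test used was limma 3.58.1 on log2(CPM + 1), with a trend in the prior variance, in R 4.3.3. CPM came from the deposited values with TMM scaling in edgeR 4.0.16, which removes any factor per library. Genes were kept with edgeR's filterByExpr on the recovered reads, at its minimum of 10 reads, which left 11985. All 8 libraries entered one fit with a term per group and no block, leaving 4 residual degrees of freedom. The 6 comparisons were MYC over WT, Zab over WT, MYC_Zab over MYC, MYC_Zab over Zab, MYC_Zab over WT, and the interaction, which is MYC_Zab over MYC minus Zab over WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale and understate the changes of low genes. Fold ratios given as "-fold" are ratios of mean CPM. In an exact permutation of 2 libraries against 2, the smallest two-sided p is 0.333, so no single gene could be tested that way.

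Gene lists were fixed before the data were examined, 30 in all with 1000 distinct genes, of which 932 were in the files. The tests were run on 26 lists with at least 5 tested members, in 6 comparisons, by limma's camera with a preset correlation of 0.01 between genes, adjusted over all 156 tests. Camera with an estimated correlation and the rotation test fry were alternatives. For each list, calls were also counted after adjustment over the list alone. Genes named in the text follow a rule also fixed then. It takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between libraries, or 5 and 5 for the interaction. It adds MYC, MAX, ADAR, ZBP1, SUPT16H, SSRP1, NCL, ODC1, CDKN1A and TOP1, and the 3 members with the smallest p of each list past the threshold. Some genes that this rule takes are not reported here.

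For a gene with 0 reads in a group, the fold is a lower bound against 3 reads over the group. For 1 to 3 reads the ratio has a 95% exact counting interval. Both cover counting error only, and since reads mostly came in twos the intervals are too narrow. Genes with near-identical copies, such as histones, ribosomal proteins with processed pseudogenes and HSPA1A with HSPA1B, are uncertain where reads could be split between copies.

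The method was tested on simulated reads for MYC over WT, drawn in twos from the real means and library sizes at the dispersion estimated from these libraries, 0.00418, with 11878 genes passing the filter. The changed genes were drawn only from genes with more reads than the filter asks, so the rates do not hold for genes with few reads. Far fewer genes were changed than were called in the real comparison. Of 67 genes changed 2-fold, 91.0% were found, against 26.9% of 67 genes changed 1.5-fold and 100% of 66 changed 4-fold. There were 6 false calls, 3.97% of the calls.

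Alternatives listed before the data were examined were other scalings (DESeq2 1.42.0 size factors, library totals, upper quartile), the DESeq2 Wald test (run on the recovered reads), other filters, a replicate block, each library left out, and fits of only the groups compared. Alternatives added after the data were seen were edgeR's quasi-likelihood test on the recovered reads, the values as deposited, pseudocounts of 0.25 and 4 CPM, removal of MYC and ADAR, only genes with 1 transcript in all libraries, the libraries labelled MYC over those labelled Zab, and the WT and MYC_Zab pairs counted as 1 sample each. A group of 1 sample, as in the last of these or with a library left out, adds nothing to the spread, which then comes from the other groups. Scaling by fly reads was not run, since no fly features are in the files used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. Gene symbols were checked against a RefSeq table of another build, GRCh38.p14, used for names only, and 18944 were current there. Coordinates are those of hg19 from the files.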

Results

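Newly made RNA was measured by TT-seq in U2OS osteosarcoma cells in a 2 by 2 design. The groups were labelled WT, Zab, MYC (MYC overexpression) and MYC_Zab (both), with 2 libraries in each. The series title names MYC, the histone chaperone FACT and Z-DNA, the left-handed form of the double helix. The comparisons asked how newly made RNA differed with MYC overexpression, with Zab, and with both. Recovered coding-exon reads were 2981234 and 2706401 in the libraries labelled WT, 1839960 and 2097530 in Zab, 3882696 and 4072059 in MYC, and 3633889 and 3799962 in MYC_Zab.

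The share of reads in coding exons set the libraries labelled Zab apart. They held 6.55 ± 0.154 coding-exon reads per 100 tags (SD, n = 2), against 13.1 ± 0.00290 in WT, 13.7 ± 0.139 in MYC and 13.5 ± 0.0423 in MYC_Zab. The summed deposited values also differed by group. They were 656816 ± 8797 in WT, 486821 ± 13756 in Zab, 964447 ± 6339 in MYC and 775934 ± 2570 in MYC_Zab (SD, n = 2). Relative to WT the sum was 1.47 in MYC, 0.741 in Zab and 1.18 in MYC_Zab. The deposited values keep a factor per library, whose basis is not given in the sources used here, and also rise with the library's number of coding reads. Whether these sums stand for amounts of RNA per cell is therefore unknown. Below, changes are relative to TMM scaling, which takes most genes as level. On the deposited scale the median gene shifted by log2 0.47 in MYC over WT, -0.63 in Zab over WT, -0.19 in MYC_Zab over MYC, 0.89 in MYC_Zab over Zab, 0.27 in MYC_Zab over WT and 0.49 in the interaction. With library totals these medians were -0.06, -0.24, 0.12, 0.26, 0.04 and 0.39.

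**Figure D1:**
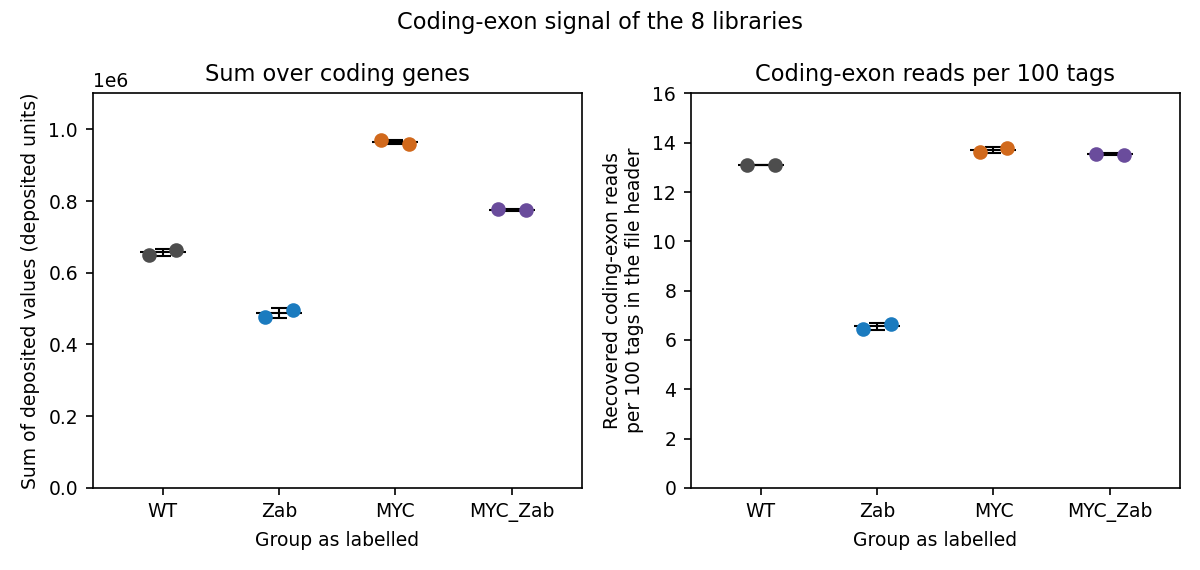
Sum of the deposited values over coding genes (left, in deposited units) and recovered coding-exon reads per 100 tags of the file header (right), for each library by labelled group. Points are libraries, and bars are the group mean ± SD (n = 2); the Zab libraries lie lowest in both panels, at means of 486821 and 6.55.

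MYC, the overexpressed transcription factor, was high only in the libraries labelled MYC among the 4 groups. It had 764 ± 17.1 CPM in WT, 966 ± 69.5 in Zab, 6592 ± 20.2 in MYC and 762 ± 14.2 in MYC_Zab (SD, n = 2). The MYC libraries were 8.63-fold above WT, while the libraries labelled MYC_Zab stood at 0.998 of WT, against a label that states overexpression. ADAR, the RNA-editing enzyme whose Z-nucleic-acid-binding domains Zαβ is named after, had 33906 ± 11.6 CPM in WT, 543 ± 33.9 in Zab, 455 ± 13.1 in MYC and 32311 ± 41.7 in MYC_Zab. ADAR took 3.51% of reads in the libraries labelled WT and 3.43% in those labelled MYC_Zab, against 0.0497% in Zab and 0.0452% in MYC. The libraries labelled WT were thus 62.5-fold above those labelled Zab. MYC lies on chromosome 8 of hg19 at 128748477 to 128755197 on the plus strand in the transcript counted in the MYC libraries, and from 128747680 in the one counted in the others. ADAR lies on the minus strand of chromosome 1 at 154554534 to 154580662 in the transcript counted in most libraries. Since both genes go against labels, each group is called by its label only. Every comparison except MYC_Zab over WT set an ADAR-high group against an ADAR-low one.

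**Figure D2:**
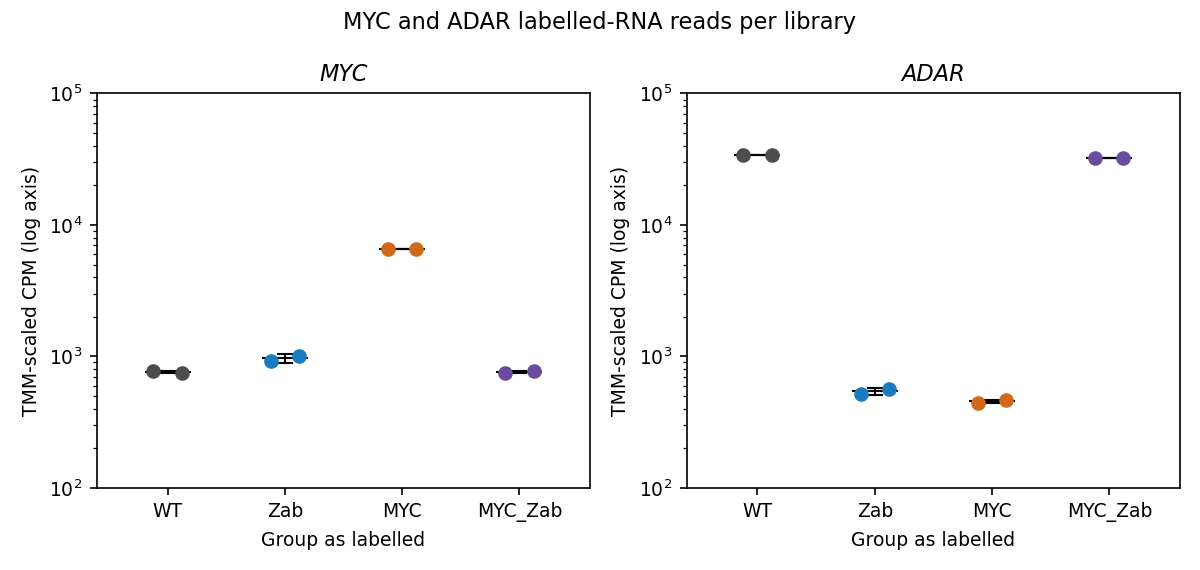
MYC (left) and ADAR (right) in TMM-scaled CPM on log axes, for each library by labelled group. Points are libraries, and bars are the group mean ± SD (n = 2); MYC stands apart in the libraries labelled MYC (6592 CPM), and ADAR is high in those labelled WT (33906) and MYC_Zab (32311).

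Replicates of a group differed by about as much as counting alone allows. The chi-square per gene of the reads was 2.048 in the WT pair, 2.042 in Zab, 1.995 in MYC and 2.023 in MYC_Zab, where 1 holds for independent reads and 2 if all reads come in twos. Among genes above 10000 reads it was 10.85 in the Zab pair (22 genes) and 3.19 in the MYC pair (56 genes), but 1.79 in WT (28 genes) and 2.47 in MYC_Zab (35 genes). A preparation sequenced again would give such values too. Beside the total of genes higher and lower in each comparison therefore stands the total with the WT and MYC_Zab pairs taken as 1 sample each. That fit takes its spread from the Zab and MYC pairs, which were near 2 as well. Among genes of 100 to 1000 reads they had 2.02 and 1.99. They too may be preparations sequenced again, so these totals do not show how far separate cultures differ. Pairs of a WT with a MYC_Zab library had 2.809 to 2.906, and pairs from other groups 27.5 to 43.9.

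In the libraries labelled MYC, genes of ribosome production and other long-known MYC targets were higher than in WT. Genes of the extracellular matrix, inflammation and the p53 response were lower. The p53 targets were lower by about as much in Zab over WT (median -0.56), and level in MYC over Zab (median 0.03). Of 60 canonical MYC targets, 48 rose and 1 fell, with a median log2 change of 0.46. SLC7A5, an amino acid transporter, rose by 1.38 ± 0.045 (SE), the cyclin CCND2 by 1.23 ± 0.043 and nucleolin, NCL, by 0.79 ± 0.036. Thrombospondin, THBS1, fell by 2.74 ± 0.065 and fibronectin, FN1, fell by 2.75 ± 0.076. All log2 changes carry SE from limma with n = 2 per group.

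Several lists moved up in MYC over WT. Translation factors and tRNA synthetases had 21 of 53 up and 12 down (22 and 13 adjusted over the list alone) and did not pass (adjusted p = 0.239 by camera). Genes of mitosis had 13 of 43 up and 3 down (12 and 3 adjusted over the list alone) and did not pass either (adjusted p = 0.0585 by camera). Canonical MYC targets (adjusted p = 1.56e-17 by camera) gave 50 rises and 1 fall adjusted over the list alone. Of 76 ribosome biogenesis genes 58 rose and 0 fell (58 and 0 adjusted over the list alone, median 0.48, adjusted p = 2.22e-17), with NOLC1 at 1.23 ± 0.062 and TCOF1, which supports ribosomal RNA transcription, at 1.06 ± 0.058. Of 22 cholesterol synthesis genes 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.96, adjusted p = 4.36e-10), among them DHCR7 at 2.12 ± 0.12 and SQLE at 1.60 ± 0.11. These 3 lists also passed with an estimated correlation. Of 38 replication-dependent histones 26 rose and 2 fell (26 and 2 adjusted over the list alone, median 0.62, adjusted p = 2.83e-12, and adjusted p = 0.0514 with an estimated correlation), with H3C2 at 1.12 ± 0.048. Another 5 lists moved up by smaller medians, none past the threshold with an estimated correlation. Glycolysis and hypoxia genes had 12 of 31 up and 4 down (12 and 4 adjusted over the list alone, median 0.22, adjusted p = 0.00708, and adjusted p = 0.073 with an estimated correlation), with GPI at 0.82 ± 0.054. S phase genes had 20 of 49 up and 4 down (20 and 4 adjusted over the list alone, median 0.24, adjusted p = 0.0104, and adjusted p = 0.107 with an estimated correlation), with the replication helicase subunits MCM4 at 0.88 ± 0.078 and MCM2 at 0.79 ± 0.079. FACT and other histone chaperones had 12 of 26 up and 4 down (12 and 5 adjusted over the list alone, median 0.19, adjusted p = 0.0167, and adjusted p = 0.107 with an estimated correlation), with SET at 0.74 ± 0.054. Heat shock genes had 12 of 23 up and 4 down (12 and 4 adjusted over the list alone, median 0.12, adjusted p = 0.0065, and adjusted p = 0.075 with an estimated correlation), with HSPA1B at 1.93 ± 0.10. Nucleotide synthesis genes had 13 of 30 up and 4 down (14 and 4 adjusted over the list alone, median 0.27, adjusted p = 0.0249, 0.0545 with library totals, and adjusted p = 0.105 with an estimated correlation), with IMPDH1 at 1.23 ± 0.11 but CTPS1 at -0.83 ± 0.064.

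Matrix and signalling lists moved down in MYC over WT. Of 41 extracellular matrix genes 28 fell and 4 rose (30 and 4 adjusted over the list alone, median -0.75, adjusted p = 1.39e-11), among them CCN2, a connective tissue growth factor, at -2.89 ± 0.062. Of 25 genes reported as MYC-repressed 16 fell and 1 rose (16 and 1 adjusted over the list alone, median -0.86, adjusted p = 9.84e-09), with the ferritin heavy chain FTH1 at -1.28 ± 0.034 and ZFP36L1 at -1.68 ± 0.066. Of 29 p53 targets 18 fell and 3 rose (20 and 3 adjusted over the list alone, median -0.56 but -0.07 on the deposited scale, adjusted p = 2.54e-05), with TP53I3 at -2.38 ± 0.13 and the cell cycle inhibitor CDKN1A at -0.89 ± 0.067. Of 23 NF-κB and inflammatory genes 14 fell and 1 rose (16 and 2 adjusted over the list alone, median -1.13, adjusted p = 5.88e-05), with the chemokine CXCL8 at -4.37 ± 0.20. Interferon-stimulated genes had 15 of 32 down and 1 up (15 and 1 adjusted over the list alone, median -0.71, adjusted p = 0.00137, and adjusted p = 0.0525 with an estimated correlation), with STAT2 at -1.46 ± 0.15. Immediate early genes had 15 of 32 down and 6 up (15 and 7 adjusted over the list alone, median -0.53 but -0.11 on the deposited scale, adjusted p = 0.00319, and adjusted p = 0.0619 with an estimated correlation), and ARC, a neuronal activity gene, rose by 1.43 ± 0.088. Ribosomal protein genes had 30 of 78 down and 12 up (31 and 12 adjusted over the list alone, median -0.07, adjusted p = 0.0237, and adjusted p = 0.0734 with an estimated correlation), a direction that flips on the deposited scale, where the median was 0.43. This call was lost without WT replicate 1 (adjusted p = 0.0551) or MYC replicate 2 (adjusted p = 0.0501). Of 5 tested epithelial markers 3 fell and 0 rose (3 and 0 adjusted over the list alone, median -0.71, adjusted p = 0.0112, and adjusted p = 0.135 with an estimated correlation), with the keratin KRT8 at -1.07 ± 0.064.

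Beside MYC, the large rises named in MYC over WT were of genes with 0 to 62 reads in WT. CAMKV, a kinase-like synaptic protein, was 55.5-fold higher, PDE1B 36.6-fold and SYT7, a vesicle calcium sensor, 11.1-fold. OPRL1, an opioid-related receptor, had 0 reads in WT and was at least 41.5-fold higher in MYC. INSIG1, a regulator of sterol synthesis, was 10-fold and KCTD12 8.79-fold higher. Of 8 tested neural markers fixed in advance, 1 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.776). After ADAR, the largest falls were MMP3, a matrix protease, at 41.0-fold lower, CXCL8 at 30.0-fold, the vasoconstrictor EDN1 at 28.9-fold, ANKRD1 at 18.3-fold, SLFN5 at 18.2-fold and the collagen COL5A1 at 17.5-fold. ESM1 had 2 reads in MYC and was 126-fold lower, with a counting interval of 35.5 to 1080. Among genes named in advance, the MYC partner MAX was 0.62 ± 0.094 and ODC1, of polyamine synthesis, 0.77 ± 0.042. The FACT subunit SSRP1 was 0.38 ± 0.050 (adjusted p = 4.65e-07), while SUPT16H was 0.14 ± 0.080 (adjusted p = 0.166) and topoisomerase TOP1 -0.09 ± 0.080 (adjusted p = 0.402), neither past the threshold, though both passed it on the deposited scale, at 0.64 and 0.41. The Z-nucleic acid sensor ZBP1 was not tested, with reads only in MYC_Zab, 0.756 CPM.

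In all, 2657 genes were higher and 2623 lower in MYC over WT by limma, 44.1% of the 11985 tested, and 750 and 1183 of them by at least 2-fold. The deposited-scale split was 5838 and 1149, and with the WT and MYC_Zab pairs taken as 1 sample each it was 1861 and 1601.

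In the libraries labelled Zab, lists of replication-dependent histones, of the unfolded protein response and of glycolysis and hypoxia were higher than in WT, though the median of the last flips on the deposited scale. The list of p53 targets was lower (adjusted p = 0.000672, and adjusted p = 0.0513 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, went from 343 CPM in WT to 3957 in Zab, log2 3.53 ± 0.048. Histone H1-4 was higher by 1.58 ± 0.035 and H1-2 by 1.53 ± 0.035, and MDM2, the p53 ubiquitin ligase, was lower by a log2 change of -2.08 ± 0.10. These libraries held the smaller coding-exon share, 6.55 per 100 tags against 13.1 in WT.

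Of the 38 histones 35 rose and 0 fell in Zab over WT (37 and 0 adjusted over the list alone, median 1.5, adjusted p = 5.02e-35 by camera), and on the deposited scale the median was 0.92. Of 32 unfolded protein response genes 21 rose and 5 fell (21 and 5 adjusted over the list alone, median 0.62, adjusted p = 2.71e-08), with CALR at 1.88 ± 0.046 and HSP90B1 at 1.47 ± 0.065, and the deposited-scale median was 0.03. Of 31 glycolysis and hypoxia genes 18 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.54, adjusted p = 2.13e-08), with PKM at 0.87 ± 0.027, ENO1 at 0.76 ± 0.023 and GAPDH at 0.54 ± 0.018, a direction that flips on the deposited scale to a median of -0.02. Ribosomal protein genes had 39 of 78 up and 24 down (39 and 25 adjusted over the list alone, median 0.12, adjusted p = 0.00114), with RPL8 at 0.93 ± 0.030, and the median flips to -0.49 on the deposited scale and -0.06 with library totals. These 4 lists also passed with an estimated correlation, but the ribosomal protein call was lost with library totals (adjusted p = 0.406). The list tests were not repeated with the trend along gene length, given below, removed. Genes of up to 5 kb had a median of 0.342 and those of 5 to 20 kb 0.131, against 1.5 for histones and 0.12 for ribosomal proteins. How much of the list rises goes with gene length is therefore unknown.

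Other lists in Zab over WT passed only with the preset correlation. Cholesterol synthesis genes had 14 of 22 up and 3 down (15 and 3 adjusted over the list alone, median 0.59 but 0.03 on the deposited scale, adjusted p = 0.000379, and adjusted p = 0.0619 with an estimated correlation), with SREBF2, a regulator of sterol synthesis, at 1.02 ± 0.082. NF-κB and inflammatory genes had 13 of 23 up and 2 down (14 and 2 adjusted over the list alone, median 0.58, adjusted p = 0.00319, and adjusted p = 0.065 with an estimated correlation), with IER3 at 1.80 ± 0.10 but REL at -2.01 ± 0.29 (-2.63 without Zab replicate 1 and -1.39 without Zab replicate 2), and the median flips to -0.02 on the deposited scale. Canonical MYC targets had 29 of 60 up and 12 down (30 and 12 adjusted over the list alone, median 0.11, adjusted p = 0.0065, and adjusted p = 0.06 with an estimated correlation), and flip to -0.47 on the deposited scale and -0.06 with library totals, where the call was lost (adjusted p = 0.315). Of the 5 epithelial markers 3 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.64 and 0.14 on the deposited scale, adjusted p = 0.0107, and adjusted p = 0.135 with an estimated correlation), with the keratins KRT18 at 0.91 ± 0.045 and KRT17 at 1.55 ± 0.14. Of the 29 p53 targets 18 fell and 6 rose (18 and 7 adjusted over the list alone, median -0.56, adjusted p = 0.000672, and adjusted p = 0.0513 with an estimated correlation), with BTG2 at -1.39 ± 0.11 and TIGAR at -1.32 ± 0.11. The 17 genes of Z-nucleic acid and double-stranded RNA sensing, ADAR among them, had 2 up and 7 down (2 and 7 adjusted over the list alone, adjusted p = 0.158). In MYC over WT the same list had 2 up and 7 down (3 and 8 adjusted over the list alone, adjusted p = 0.0852).

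SPRR2D, an epidermal envelope gene, had 2 reads in WT and was 402-fold higher in Zab, with a counting interval of 105 to 3170. Other large rises were OASL at 17.9-fold, OLAH at 14.8-fold, CRELD2 at 12.7-fold, OSCAR at 11.6-fold, SDF2L1 at 8.61-fold and DEPP1 at 8.53-fold. With WT replicate 1 or WT replicate 2 left out, the log2 change of OASL by limma was 3.07 or 4.42 (3.75 with all) and that of OLAH 4.56 or 2.71 (3.64 with all). CRELD2 and SDF2L1 encode endoplasmic reticulum proteins. After ADAR, the largest falls were of genes with few reads in Zab. SAMD9 had 2 reads there and was 41.9-fold lower (interval 10.8 to 332), STXBP3 had 2 and was 31.4-fold lower (8.0 to 249), FAM161A had 2 and was 18.7-fold lower (4.70 to 150), and MYBL1 had 3 and was 14.5-fold lower (4.41 to 67.0). ZNF33A had 0 reads in Zab and was at least 12.7-fold lower. SMC6, of DNA repair, was 12-fold and the kinase PIK3CA 10.7-fold lower. With Zab replicate 1 or Zab replicate 2 left out, PIK3CA was by limma at log2 -2.52 or -3.77 (-3.14 with all) and MYBL1 at -2.23 or -3.60 (-2.90 with all). Among genes named in advance, MYC was 0.34 ± 0.041, SSRP1 0.41 ± 0.050 and ODC1 0.49 ± 0.042, and these 3 flip on the deposited scale, to -0.27, -0.20 and -0.12. SUPT16H was -0.81 ± 0.080, TOP1 -1.08 ± 0.080 and CDKN1A -0.46 ± 0.067, while MAX was -0.04 ± 0.094 and NCL -0.03 ± 0.036, neither past the threshold (adjusted p = 0.725 and 0.594). Both passed it on the deposited scale, at -0.65 and -0.63, and NCL also with library totals, at -0.20; without 1 library, MAX ran from -0.16 to 0.07 and NCL from -0.08 to 0.03.

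Fold changes in Zab over WT ran with the length of the gene, as Spearman's rho across genes, which are not independent replicates, was -0.296 with genomic span and -0.222 with exon length. The median log2 change went from 0.34 in 1169 genes of up to 5 kb to -0.44 in 803 genes over 200 kb. The rho was 0.25 with mean expression. In all, 2696 genes were higher and 3243 lower, 49.6% of those tested, and 557 and 1528 by at least 2-fold. Deposited values gave 575 and 6882, and with the WT and MYC_Zab pairs taken as 1 sample each in the joint fit the split was 1896 and 2051. After removal of the length trend it was 3223 and 2368.

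**Figure D3:**
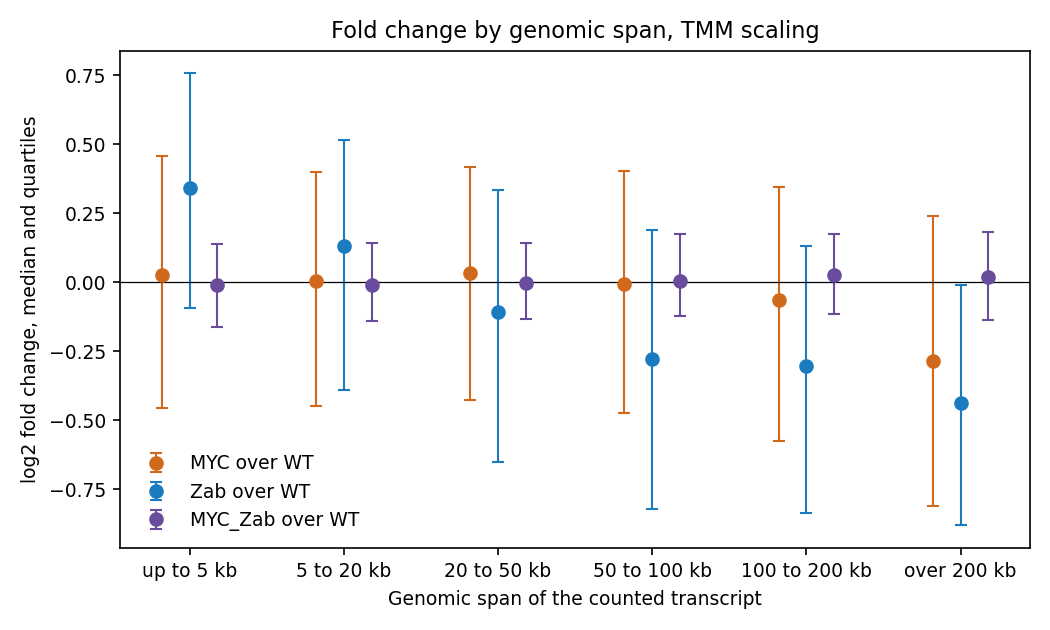
Log2 fold change on the TMM scale (vertical) by genomic span of the counted transcript in kb (horizontal), for 3 comparisons. Points are medians over genes and bars the quartiles; in Zab over WT the median goes from 0.34 up to 5 kb to -0.44 over 200 kb, and on the deposited scale all points of a comparison move together.

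In the libraries labelled MYC_Zab, MYC targets were lower, and matrix and inflammatory genes higher, than in the libraries labelled MYC. The label states MYC overexpression in both groups, yet MYC itself was 8.65-fold lower in MYC_Zab, log2 -3.11 ± 0.041. Of 60 canonical MYC targets 51 fell and 2 rose, with a median of -0.59. CCN2 was higher by 2.97 ± 0.062, THBS1 by 2.83 ± 0.065 and FN1 by 2.77 ± 0.076. ADAR was 71.1-fold higher.

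Lists that passed with both correlations in MYC_Zab over MYC were the canonical MYC targets (51 falls and 2 rises adjusted over the list alone, adjusted p = 1.86e-21 by camera) and 10 others. Of 76 ribosome biogenesis genes 62 fell and 0 rose (63 and 0 adjusted over the list alone, median -0.55), with NOLC1 at -1.36 ± 0.062. Of 38 histones 28 fell and 1 rose (28 and 1 adjusted over the list alone, median -0.94), and of 22 cholesterol synthesis genes 19 fell and 0 rose (19 and 0 adjusted over the list alone, median -1.03). Nucleotide synthesis genes had 18 of 30 down and 1 up (18 and 2 adjusted over the list alone, median -0.37), and heat shock genes 14 of 23 down and 5 up (14 and 5 adjusted over the list alone, median -0.27). Of 41 matrix genes 30 rose and 3 fell (30 and 4 adjusted over the list alone, median 0.76), of 25 reported MYC-repressed genes 17 rose and 1 fell (18 and 1, median 0.87, also adjusted over the list alone), and of 29 p53 targets 20 rose and 3 fell (20 and 3 adjusted over the list alone, median 0.60). NF-κB and inflammatory genes had 15 of 23 up and 2 down (15 and 2 adjusted over the list alone, median 1.01), and interferon-stimulated genes 15 of 32 up and 1 down (15 and 1 adjusted over the list alone, median 0.70). Their adjusted p ran from 1.76e-19 for ribosome biogenesis to 0.000672 for the interferon list, and 0.0216 to 0.0483 with an estimated correlation.

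Lists past the threshold only with the preset correlation are given with both values. Glycolysis and hypoxia had 15 of 31 down and 3 up (15 and 3 adjusted over the list alone, adjusted p = 0.00114, and adjusted p = 0.0514 with an estimated correlation), a direction shared by its deposited-scale median of -0.47. S phase genes had 19 of 49 down and 2 up (19 and 2 adjusted over the list alone, adjusted p = 0.00286, and adjusted p = 0.0785 with an estimated correlation). Translation factors and tRNA synthetases had 26 of 53 down and 12 up (27 and 12 adjusted over the list alone, adjusted p = 0.00674, 0.0747 with library totals, and adjusted p = 0.0619 with an estimated correlation), with EIF3B at -0.86 ± 0.043. FACT and histone chaperones had 13 of 26 down and 5 up (13 and 5 adjusted over the list alone, adjusted p = 0.00817, and adjusted p = 0.0864 with an estimated correlation), with SET at -0.88 ± 0.054 and NPM1 at -0.34 ± 0.036. Genes of mitosis had 17 of 43 down and 5 up (17 and 5 adjusted over the list alone, adjusted p = 0.0293, 0.072 with library totals, and adjusted p = 0.135 with an estimated correlation), with BIRC5 at -1.29 ± 0.099 and PLK1 at -0.99 ± 0.087. Immediate early genes had 15 of 32 up and 7 down (15 and 9 adjusted over the list alone, adjusted p = 0.00574, and adjusted p = 0.0685 with an estimated correlation), with FOSL1 at 1.39 ± 0.089. Of the 5 epithelial markers 3 rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.0294, 0.0511 without MYC replicate 1, and adjusted p = 0.178 with an estimated correlation).

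Among the largest rises after ADAR in MYC_Zab over MYC were MMP3 at 40.2-fold, CXCL8 at 27.1-fold, COL5A1 at log2 4.08, SLFN5 at 19.2-fold, ANKRD1 at 17.1-fold and INHBA, an activin subunit, at 16.2-fold. ESM1, with 2 reads in MYC, was 137-fold higher (interval 38.3 to 1160). Among the largest falls were CAMKV at 39.9-fold, PDE1B at 37.0-fold, INSIG1 at 12.6-fold, GPRC5B at 12.2-fold, PDZRN3 at 10.8-fold and KCTD12 at 9.55-fold. By limma GPRC5B was at log2 -3.94 without MYC_Zab replicate 1 and -2.49 without MYC_Zab replicate 2 (-3.22 with all), and PDZRN3 ran from -3.61 to -2.71 (-3.16 with all) with 1 library left out. OPRL1 had 3 reads in MYC_Zab and was 56.9-fold lower (interval 18.8 to 273). Among genes named in advance, SSRP1 was -0.46 ± 0.050, SUPT16H -0.33 ± 0.080, MAX -0.61 ± 0.094, NCL -0.88 ± 0.036, ODC1 -1.09 ± 0.042 and CDKN1A 0.87 ± 0.067, and TOP1 was 0.05 ± 0.080 (adjusted p = 0.626). In all, 2642 genes were higher and 2699 lower, 1237 and 706 by at least 2-fold. On the deposited scale the split was 1853 and 4006, and with the WT and MYC_Zab pairs taken as 1 sample each it was 1601 and 1962.

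In the libraries labelled MYC_Zab, lists of histones, of the unfolded protein response and of glycolysis and hypoxia were lower than in the libraries labelled Zab, though the medians of the last 2 flip on the deposited scale, and p53 targets were higher. HSPA5 was 12.3-fold lower, log2 -3.62 ± 0.048. Histones H1-4 and H1-2 were at -1.81 ± 0.035 and -1.80 ± 0.035, and MDM2 was 4.84-fold higher. ADAR was 59.5-fold higher, and MYC was at -0.34 ± 0.041, which flips to 0.54 on the deposited scale. The coding-exon share was 13.5 per 100 tags in MYC_Zab against 6.55 in Zab.

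Of the 38 histones 37 fell and 0 rose in MYC_Zab over Zab (37 and 0 adjusted over the list alone, median -1.80, adjusted p = 1.80e-37 by camera), and the deposited-scale median was -0.93. The unfolded protein response list had 20 of 32 down and 5 up (20 and 5 adjusted over the list alone, median -0.53, adjusted p = 2.13e-08), flipping to 0.34 on the deposited scale, with CALR at -1.93 ± 0.046. Glycolysis and hypoxia genes had 18 of 31 down and 1 up (19 and 2 adjusted over the list alone, median -0.69, adjusted p = 1.76e-08), flipping to 0.19 there. Ribosomal protein genes had 46 of 78 down and 20 up (47 and 20 adjusted over the list alone, median -0.25, adjusted p = 3.19e-06), flipping to 0.63, and canonical MYC targets 35 of 60 down and 9 up (35 and 9 adjusted over the list alone, median -0.26, adjusted p = 1.37e-05), flipping to 0.62. HSPE1, a mitochondrial chaperonin in the latter list, rose by 1.49 ± 0.093. Of 29 p53 targets 20 rose and 4 fell (20 and 6 adjusted over the list alone, median 0.67, adjusted p = 0.000276), with RPS27L at 1.59 ± 0.12. These 6 lists passed with an estimated correlation too. Their tests were not repeated after removal of the length trend either.

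Further lists in MYC_Zab over Zab flip on the deposited scale as well. Cholesterol synthesis genes had 13 of 22 down and 1 up (13 and 1 adjusted over the list alone, adjusted p = 0.000287, and adjusted p = 0.0618 with an estimated correlation), with a median of -0.55 against 0.32 on the deposited scale. NF-κB and inflammatory genes had 13 of 23 down and 2 up (13 and 2 adjusted over the list alone, adjusted p = 0.00297, and adjusted p = 0.0645 with an estimated correlation), with -0.72 against 0.15. Epithelial markers had 3 of 5 down and 1 up (3 and 1 adjusted over the list alone, adjusted p = 0.00739, and adjusted p = 0.123 with an estimated correlation), with -0.72 against 0.16. Nucleotide synthesis had 14 of 30 down and 4 up (14 and 4 adjusted over the list alone, adjusted p = 0.0104, 0.0951 with library totals, and adjusted p = 0.0785 with an estimated correlation), with -0.29 against 0.58. Heat shock genes had 13 of 23 down and 7 up (13 and 8 adjusted over the list alone, adjusted p = 0.0384, 0.0674 with library totals, and adjusted p = 0.131 with an estimated correlation), with -0.41 against 0.46 and an adjusted p of 0.0528 without Zab replicate 1, while HSP90AA1 rose by 1.13 ± 0.037. S phase genes had 19 of 49 down and 7 up (19 and 7 adjusted over the list alone, adjusted p = 0.043, 0.153 with library totals, and adjusted p = 0.168 with an estimated correlation), with -0.15 against 0.72, and 0.06 with library totals. The S phase call was lost without Zab replicate 2 (adjusted p = 0.105) or MYC_Zab replicate 1 (adjusted p = 0.0504).

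Among the largest rises in MYC_Zab over Zab after ADAR, SGO2, which protects chromosome cohesion, was 14.5-fold higher, SMC6 14.5-fold, the ciliary and centrosomal gene CEP290 14-fold and ESCO1, a cohesin acetyltransferase, 12.6-fold. With Zab replicate 1 or Zab replicate 2 left out, SGO2 was by limma at log2 4.65 or 2.89 (3.76 with all) and CEP290 at 4.69 or 2.49 (3.58 with all), and ESCO1 ran from 2.90 to 4.05 (3.47 with all). SAMD9 and STXBP3, with 2 reads each in Zab, were 61.8-fold (interval 16 to 485) and 50.6-fold (13 to 396) higher, and ZNF33A was at least 13.7-fold higher. The largest falls were SPRR2D at 127-fold, OSCAR at 27.4-fold, OASL at 22.6-fold, HSPA5, PI3 at 11.9-fold, CRELD2 at 9.71-fold, SDF2L1 at 8.51-fold and DEPP1 at 8.40-fold. Among genes named in advance SUPT16H was 0.62 ± 0.080, TOP1 1.05 ± 0.080 and CDKN1A 0.44 ± 0.067. SSRP1 was -0.49 ± 0.050 and ODC1 -0.81 ± 0.042, both flipping on the deposited scale to 0.39 and 0.08. MAX was 0.06 ± 0.094 and NCL -0.07 ± 0.036, neither past the threshold (adjusted p = 0.622 and 0.137). Both passed it as higher on the deposited scale, at 0.94 and 0.82, and with library totals, at 0.27 and 0.14, but NCL passed as lower by DESeq2 (-0.11), by edgeR (-0.10) and without Zab replicate 1 (-0.12). Fold changes ran with gene length here too, with a rho of 0.299 with genomic span and 0.246 with exon length. In all, 3217 genes were higher and 2711 lower, 1643 and 511 by at least 2-fold, and after removal of the length trend the split was 2261 and 3427, with 77.3% of the calls kept. On the deposited scale the split was 8807 and 237, and with the WT and MYC_Zab pairs taken as 1 sample each it was 2044 and 1924.

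**Figure D4:**
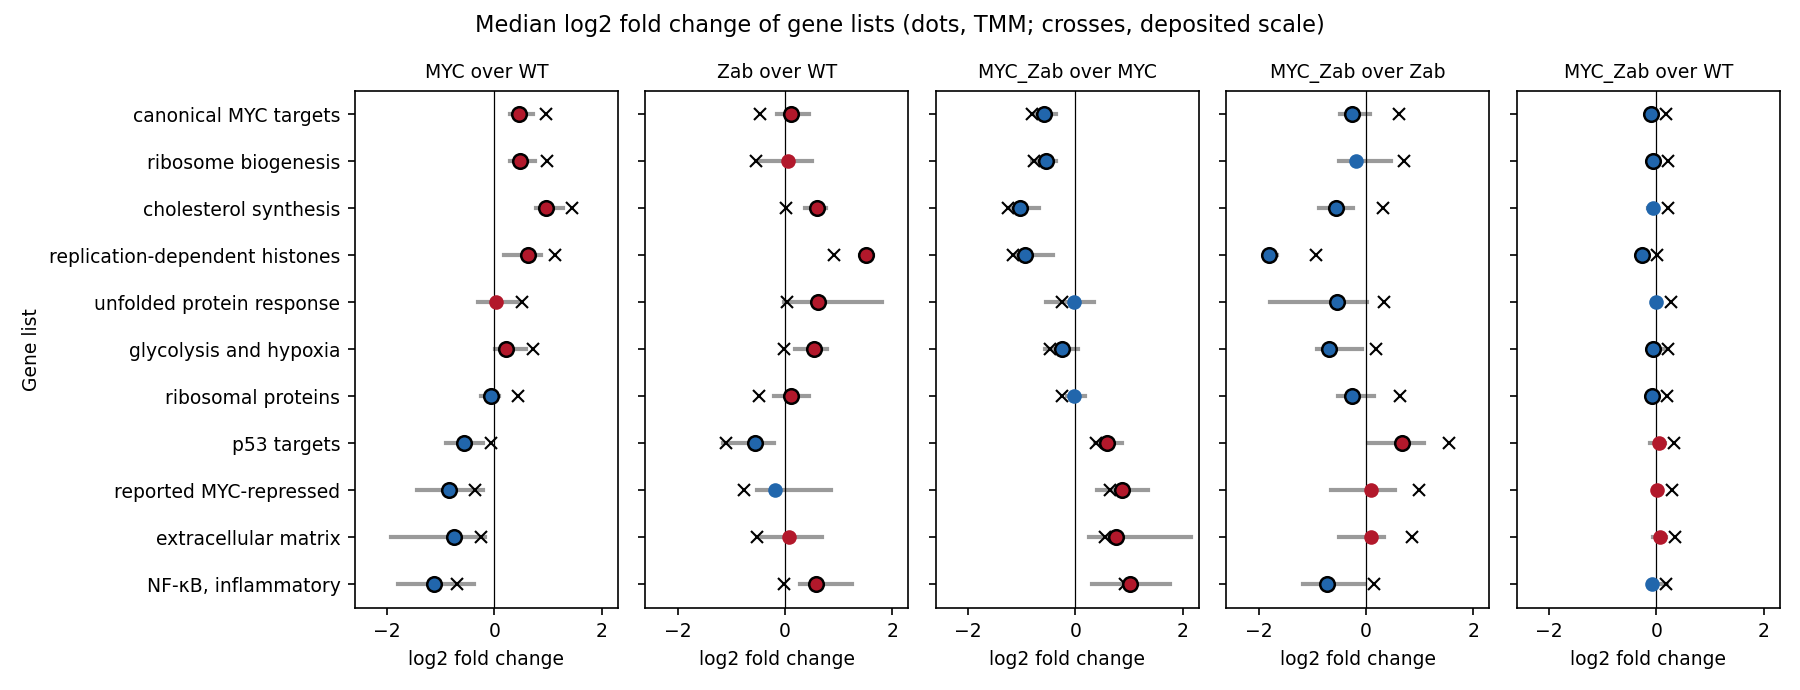
Median log2 fold change of 11 gene lists (vertical) in 5 comparisons, with TMM scaling (dots, outlined where camera's adjusted p is under 0.05; grey bars, quartiles) and on the deposited scale (crosses). Histones stand at 1.5 in Zab over WT and -1.80 in MYC_Zab over Zab, and crosses on the other side of 0 from their dot mark lists whose direction flips on the deposited scale, such as ribosomal proteins (-0.07 against 0.43 in MYC over WT).

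The libraries labelled MYC_Zab and WT were close to each other. By limma 16 genes were higher and 53 lower in MYC_Zab over WT, 0.576% of those tested, of which 2 and 1 by at least 2-fold. ADAR was at 0.953 of WT and MYC at 0.998. List medians below 0 passed camera for 8 lists with TMM scaling, and all 8 medians were above 0 on the deposited scale. Of 38 histones 13 fell and 0 rose (26 and 0 adjusted over the list alone, median -0.26, adjusted p = 5.84e-37 by camera), against 0.01 on that scale. Across genes, the log2 change in MYC_Zab over WT had a rho of -0.127 with mean expression and 0.119 with exon length. How much of the small list medians goes with these trends was not tested.

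Ribosomal protein genes had 10 of 78 down and 2 up in MYC_Zab over WT (24 and 2 adjusted over the list alone, median -0.08 and 0.19 on the deposited scale, adjusted p = 1.92e-12). Canonical MYC targets had 5 of 60 down and 1 up (17 and 1 adjusted over the list alone, median -0.10 and 0.18 on the deposited scale, adjusted p = 1.08e-09), and translation factors 2 of 53 down and 0 up (14 and 0 adjusted over the list alone, median -0.09 and 0.19 on the deposited scale, adjusted p = 1.24e-09). Heat shock genes had 4 of 23 down and 1 up (8 and 1 adjusted over the list alone, median -0.12 and 0.15 on the deposited scale, adjusted p = 2.49e-08), and nucleotide synthesis 0 of 30 either way (5 and 0 adjusted over the list alone, median -0.15 and 0.12 on the deposited scale, adjusted p = 7.97e-07). Glycolysis and hypoxia had 4 of 31 down and 0 up (6 and 0 adjusted over the list alone, median -0.07 and 0.21 on the deposited scale, adjusted p = 0.00105, 0.284 by fry, and adjusted p = 0.0514 with an estimated correlation). Ribosome biogenesis had 1 of 76 down and 0 up (2 and 0 adjusted over the list alone, median -0.06 and 0.22 on the deposited scale, adjusted p = 0.00216, 0.0987 without WT replicate 1, 0.0549 by fry, and adjusted p = 0.083 with an estimated correlation). Deposited values gave 1749 higher and 3 lower. With both pairs taken as 1 sample each, limma called 0 and 0, with 183 genes at an unadjusted p under 0.05, but this sets 1 sample against 1, with all the spread from the Zab and MYC pairs, so it does not bear on the spread within WT or MYC_Zab. With all libraries edgeR called 49 and 97 on the recovered reads. Without 1 of the 4 libraries, which leaves 1 sample in its group and takes the spread from the other 3 groups, limma called 6 and 26 (WT replicate 1 left out), 7 and 21 (WT replicate 2), 4 and 25 (MYC_Zab replicate 1), and 3 and 19 (MYC_Zab replicate 2).

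With MYC_Zab close to WT, the interaction is near MYC over WT plus Zab over WT with the sign turned. Since MYC_Zab had MYC at 0.998 and ADAR at 0.953 of WT, it cannot tell whether Zab acts differently with MYC overexpression. The difference between the effects of Zab with and without MYC overexpression, as labelled, was tested by the interaction. It was positive for 3508 genes and negative for 2876, 53.3% of those tested, with 5044 and 1837 on the deposited scale, 2326 and 2194 with the pairs taken as 1 sample each, and 2580 and 3547 after removal of the length trend. Histones (0 of 38 positive and 34 negative, 0 and 35 adjusted over the list alone) had a median of -2.39 (adjusted p = 1.54e-31) and p53 targets (23 of 29 positive and 4 negative, 23 and 4 adjusted over the list alone) 1.14 (adjusted p = 3e-06), and both passed with an estimated correlation. HSPA5 stood at -4.17 ± 0.068, GADD45A, a p53 target of the DNA damage response, at 3.17 ± 0.17, and BOP1 and PES1, of ribosome assembly, at -2.24 ± 0.10 and -1.89 ± 0.082.

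Comparisons that share no library ran weakly against each other across the 11985 genes, but they do not compare 1 step in 2 backgrounds, since MYC and ADAR did not change in the same direction in both. MYC over WT and MYC_Zab over Zab had Pearson's r of -0.172 and Spearman's rho of -0.186, with the same sign in 43.2% of genes. Zab over WT and MYC_Zab over MYC had -0.213 and -0.220. Comparisons that share libraries correlate by construction, so simulated unchanged groups stand beside them. MYC over WT against MYC_Zab over MYC had r -0.939 (simulated -0.501) and covariance -0.614 (simulated -0.0404), with 2255 genes higher in the first and lower in the second and 2218 the reverse, where independent lists give 598.4 and 578.2. Zab over WT against MYC_Zab over Zab had r -0.939 (simulated -0.501) and covariance -0.609 (simulated -0.0404), with 2285 and 2765 such genes against 609.8 and 870.5. MYC over WT against Zab over WT had r 0.239 (simulated 0.502) and covariance 0.153 (simulated 0.0405), with 1162 genes higher in both and 865 lower in both against 597.7 and 709.8. Part of each excess may come from the shared libraries, but those alone gave only the simulated covariances. MYC_Zab was close to WT, with an SD of the log2 change of 0.283 across genes. MYC_Zab over MYC is thus near MYC over WT with the sign turned, and MYC_Zab over Zab near Zab over WT turned. These mirrored comparisons are not separate evidence. For the same reason, the r of -0.172 and -0.213 stand near the 0.239 of MYC over WT against Zab over WT with the sign turned. Genes are not independent replicates, and no p is given for these.

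Lists fixed in advance and not yet described gave smaller or mixed changes. Genes of polymerase pausing and elongation had 10 of 35 up and 2 down in MYC over WT (10 and 2 adjusted over the list alone, adjusted p = 0.217), and topoisomerase genes 6 of 17 up and 4 down (6 and 4 adjusted over the list alone, adjusted p = 0.65). Nuclear genes of oxidative phosphorylation had 10 of 43 up and 6 down there (10 and 6 adjusted over the list alone, adjusted p = 0.429), and circadian clock genes 9 of 19 up and 5 down (9 and 6 adjusted over the list alone, adjusted p = 0.308). None of these 4 passed in any of the 6 comparisons. Of 4 tested blood cell markers 2 fell and 0 rose in MYC over WT (4 and 0 adjusted over the list alone), too few for a list test.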

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

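The tests of exchanged labels, of an interferon response and of MYC overexpression were chosen only after the results they measure were seen; those of a shared library, of gene length and of depth were chosen before. The difference between the effects of Zab in MYC and in WT cells, as labelled, was positive for 3508 genes and negative for 2876 by limma's interaction test, which also gave the values for lists and single genes in this paragraph and the next. Since MYC_Zab was close to WT, with MYC at 0.998 of it, these values do not show that an effect of Zab depended on MYC overexpression. Gene lists with a negative median difference were histones (-2.388), cholesterol synthesis (-1.488), glycolysis and hypoxia (-0.877), the unfolded protein response (-0.852), canonical MYC targets (-0.696) and ribosome biogenesis (-0.561). Lists with a positive one were p53 targets (1.137) and extracellular matrix (0.849). S phase genes (-0.441, or -0.061 on the deposited scale; adjusted p = 0.0754 with an estimated correlation), nucleotide synthesis (-0.385, or -0.015 on the deposited scale; 0.0566) and reported MYC-repressed genes (1.019, 0.0785) passed only with the preset correlation. So did ribosomal proteins (-0.151, adjusted p = 0.073 with an estimated correlation) and heat shock genes (-0.144, 0.0921), whose medians flip to 0.23 and 0.22 on the deposited scale and 0.11 and 0.12 with library totals; the heat shock call was lost on the deposited scale (adjusted p = 0.0523).

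Among single genes the difference was 12.112 for ADAR, 6.269 for MMP3, 5.805 for INHBA, -4.772 for the heat shock gene HSPA6, -4.715 for INSIG1 and -4.382 for PDE1B. SAMD9 (6.501), ESM1 (6.295) and SPRR2D (-6.51) had 2 reads in 1 of the groups, so their fitted sizes depend on the added 1 CPM. Genes named in advance had -3.449 for MYC, -0.563 for MAX (call lost with library totals, at -0.299, and on the deposited scale, at -0.184), 0.482 for SUPT16H, -0.871 for SSRP1, -0.856 for NCL, -1.577 for ODC1, 1.332 for CDKN1A and 1.134 for TOP1.

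ADAR reads ran against the labels of the WT and Zab groups, if Zab carries ADAR sequence. The lowest WT library had 59.8 times the ADAR of the highest Zab library, which is what exchanged labels of the WT and Zab libraries would give, if the Zab construct carries ADAR sequence that these reads cover. An interferon response, of which ADAR is a target, is argued against for WT over Zab. There interferon-stimulated genes had a median log2 difference of -0.46 (SD 1.59), against 5.96 for ADAR. In the comparisons with MYC the list moved with ADAR, with medians of 0.70 (SD 0.745) in MYC_Zab over MYC and -0.71 (SD 0.782) in MYC over WT. ADAR was 71.1-fold higher in the first and 74.6-fold lower in the second, so there the argument rests on size alone. What the Zab label stands for, and whether the construct holds that sequence, is not given in the sources used here, so an exchange, a meaning of the label other than a Zαβ construct and a biological change of ADAR all stay open.

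The libraries labelled MYC_Zab resembled those labelled WT. A library deposited under both labels is argued against, since the lowest chi-square per gene of the WT with MYC_Zab pairs was 2.809, above the 2.048 of the highest replicate pair. MYC at 0.998 of WT is what cells without MYC overexpression would give. A wrong label, a loss of overexpression in those cells and a Zab effect that brings MYC back to its WT level stay open, and none of the data used here decides between them.

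Many genes differed between the libraries labelled Zab and WT. A trend with exon length or genomic span as the whole cause is argued against, since 77.8% of the calls were kept after that trend, which held 9.53% of the variance, was removed, although the split went from 2696 and 3243 to 3223 and 2368. Lower depth is argued against too, since 86.4% of the calls were kept with all libraries thinned to 1839960 reads. Base composition was not tested, because the genome sequence of the build was not used here. An effect of Zab stays open as untested, as does an exchange of labels.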

How the results depend on the processing

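The deposited values, edgeR, pseudocounts, the genes with 1 kept transcript, removal of MYC and ADAR and the pairs taken as 1 sample were tests chosen only after the data were seen. Below, a reversal is a change of sign, or of camera's direction for a list, whether or not both settings gave a call. Named genes stayed called in the same direction, or stayed uncalled in either direction, in 1755 tests under other settings and 1407 with a library left out; in other settings 10 lost and 8 gained a call, and 21 reversed. NCL in MYC_Zab over Zab gained a call without Zab replicate 1. Single lists kept theirs in 399 tests, lost the call in 46 and reversed in 17, and with a library left out 353 kept it and 7 lost it. In simulated reads at the real depth and 2 libraries per group, 26.9% of 1.5-fold changes in well-covered genes were found, and depth was not varied there. Scaling by fly reads and removal of mitochondrial or structured non-coding RNA were not run, since no such features are in the files used here. Where no reason is given, the cause was not tested.

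On the deposited scale all genes of a library shift with its factor and its number of coding reads together. There, higher and lower calls were 5838 and 1149 in MYC over WT and 575 and 6882 in Zab over WT. They were 8807 and 237 in MYC_Zab over Zab and 1749 and 3 in MYC_Zab over WT, and the interaction was negative for 1837. With only genes with 1 kept transcript, fewer genes were tested and calls were 1662 and 1405 in MYC over WT, 1753 and 1626 in Zab over WT, 1362 and 1702 in MYC_Zab over MYC, 1537 and 1752 in MYC_Zab over Zab, 1727 and 1862 in the interaction and 8 higher in MYC_Zab over WT. With the pairs taken as 1 sample each, which leaves fewer samples and takes all the spread from the Zab and MYC pairs, 1601 were lower in MYC over WT, 2051 lower in Zab over WT, 1601 higher in MYC_Zab over MYC, 2044 higher in MYC_Zab over Zab and 2326 positive in the interaction, and limma called 0 and 0 in MYC_Zab over WT (183 at an unadjusted p under 0.05, and 49 and 97 by edgeR with all libraries). Library totals gave 1742 lower in MYC_Zab over Zab and 32 lower in MYC_Zab over WT. In MYC_Zab over WT calls were 4 and 13 with no filter, 49 and 97 by edgeR, 42 and 84 with only the 2 groups compared, and 114 lower by DESeq2; with 1 library left out they ran from 3 to 7 higher and 19 to 26 lower.

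Lists past the threshold were 17, 9, 18, 12, 8 and 13 in MYC over WT, Zab over WT, MYC_Zab over MYC, MYC_Zab over Zab, MYC_Zab over WT and the interaction. With an estimated correlation they were 7 in MYC over WT, 4 in Zab over WT, 11 in MYC_Zab over MYC, 6 in MYC_Zab over Zab and 8 in the interaction. By fry, which does not compare a list with other genes, they were 21 in Zab over WT, 23 in MYC_Zab over Zab and 22 in the interaction. On the deposited scale they were 15 in Zab over WT and 15 in MYC_Zab over WT. Lists whose direction by camera reversed on the deposited scale, with its adjusted p, were ribosomal proteins in MYC over WT (4.23e-09), Zab over WT (9.95e-08), MYC_Zab over Zab (5.85e-13), MYC_Zab over WT (1.97e-20) and the interaction (0.148, and 0.82 with library totals), and canonical MYC targets in Zab over WT (0.0048), MYC_Zab over Zab (0.000114) and MYC_Zab over WT (0.000479). In MYC_Zab over Zab so did nucleotide synthesis (0.293), S phase (0.757) and heat shock (0.441), and in MYC_Zab over WT ribosome biogenesis (0.000168), nucleotide synthesis (0.988), translation factors (4.07e-05), heat shock (0.133) and glycolysis (0.0255). Medians of other lists crossed 0 on that scale too, without a reversal by camera.

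Genes that reversed on the deposited scale, with their log2 change there, were TOP1 (0.41), RPLP0 (0.059) and KRT18 (0.086) in MYC over WT, and MYC (-0.269), SSRP1 (-0.199), ODC1 (-0.119) and GAPDH (-0.064) in Zab over WT. In MYC_Zab over Zab they were MYC (0.542), SSRP1 (0.393), NCL (0.817, and 0.145 with library totals), ODC1 (0.076), FKBP4 (0.244), SHMT2 (0.021), RRM2 (0.005), RPS2 (0.087), MCM7 (0.113), HSPA8 (0.158), FDFT1 (0.022), GAPDH (0.192) and KRT8 (0.16). Calls gained, with the log2 change, were SUPT16H in MYC over WT (0.636), MAX (-0.646) and NCL (-0.632) in Zab over WT and MAX in MYC_Zab over Zab (0.937) on the deposited scale, NCL in Zab over WT (-0.2) and MAX in MYC_Zab over Zab (0.27) with library totals, and NCL in MYC_Zab over Zab by DESeq2 (-0.114) and edgeR (-0.098). Calls lost on the deposited scale included RPL13A in MYC over WT (-0.01), SLC7A5 (0.042), FDPS (0.154) and KRT8 (0.031) in Zab over WT, KRT18 in MYC_Zab over MYC (0.055), NFKBIA (-0.266) and ENO1 (-0.034) in MYC_Zab over Zab and MAX in the interaction (-0.184, and -0.299 with library totals). With 1 library left out, correlations of effects ran from -0.942 to -0.909 (MYC over WT with MYC_Zab over MYC), -0.172 to -0.161 (MYC over WT with MYC_Zab over Zab), 0.225 to 0.288 (MYC over WT with Zab over WT), -0.213 to -0.198 (Zab over WT with MYC_Zab over MYC) and -0.946 to -0.907 (Zab over WT with MYC_Zab over Zab).

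With replicate number as a block, calls were 2666 and 2621 in MYC over WT, 2700 and 3241 in Zab over WT, 2637 and 2701 in MYC_Zab over MYC, 3214 and 2714 in MYC_Zab over Zab, 16 and 58 in MYC_Zab over WT and 3508 and 2872 in the interaction. With the trend along gene length removed, calls were 3031 and 2271 in MYC over WT, 3223 and 2368 in Zab over WT, 2180 and 3193 in MYC_Zab over MYC, 2261 and 3427 in MYC_Zab over Zab, 11 and 56 in MYC_Zab over WT and 2580 and 3547 in the interaction. Correlations of replicate differences between groups ran from -0.026 to 0.01. Replicates differed by about as much as counting alone allows, so these correlations cannot tell whether replicate numbers pair the samples.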

Other observations

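The test on canonical MYC targets below was written before its result. The families of genes were chosen only after the data were seen, by the start of their symbols, 12 in all and each tested in 6 comparisons. Their p-values are therefore not separate support for changes already seen. Nor are the mirrored comparisons, since MYC_Zab was close to WT. Genes of protein folding in the endoplasmic reticulum moved with HSPA5: of 12 tested, 11 rose and 0 fell in Zab over WT, with a median log2 change of 1.32 (0.72 on the deposited scale; adjusted p = 1.85e-10 by camera, and adjusted p = 0.0652 with an estimated correlation), and 9 fell and 0 rose in MYC_Zab over Zab, with a median of -1.45 (-0.58 on the deposited scale; adjusted p = 1.85e-10, and adjusted p = 0.0652 with an estimated correlation). Centrosomal CEP genes went the other way, with 18 of 34 down and 4 up in Zab over WT (median -0.90, adjusted p = 0.00792, and adjusted p = 0.206 with an estimated correlation). In MYC_Zab over Zab 19 rose and 4 fell (median 0.97, adjusted p = 0.00265 by camera, and adjusted p = 0.163 with an estimated correlation). The family tests were not repeated with the trend along gene length removed. In Zab over WT genes over 200 kb had a median of -0.44 and those of up to 5 kb 0.34. How much of these family changes goes with gene length, or with the smaller coding-exon share of the Zab libraries, is unknown.

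Genes of the mitochondrial ribosome had 30 of 78 up and 3 down in MYC over WT (median 0.32, adjusted p = 0.00197, and adjusted p = 0.083 with an estimated correlation), and 37 down and 4 up in MYC_Zab over MYC (median -0.35, adjusted p = 0.000147, and adjusted p = 0.0652 with an estimated correlation). Splicing factor genes of the SF3 and SRSF families had 15 of 20 up and 0 down in MYC over WT (median 0.39, adjusted p = 0.000102, and adjusted p = 0.121 with an estimated correlation), and 16 down and 1 up in MYC_Zab over MYC (median -0.45, adjusted p = 4.51e-05, and adjusted p = 0.121 with an estimated correlation). Collagen genes had 12 of 24 down and 1 up in MYC over WT (median -0.73, adjusted p = 0.003, and adjusted p = 0.12 with an estimated correlation), and 13 up and 1 down in MYC_Zab over MYC (median 0.91, adjusted p = 0.000347, and adjusted p = 0.083 with an estimated correlation).

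Of the 72 tests of these families, 22 passed with the preset correlation and 0 with an estimated one. Zinc finger, solute carrier, proteasome and CCT chaperonin genes passed in at least 1 comparison each, among them the CCT genes in MYC_Zab over WT, with 2 of 8 down and 0 up (median -0.20, flipping to 0.08 on the deposited scale; adjusted p = 4.81e-10, and adjusted p = 0.083 with an estimated correlation). Kinesins, protocadherins and semaphorins passed in none of the 6.

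A hypothesis was that the rise of canonical MYC targets in MYC over WT may follow from the ADAR difference between these libraries. The libraries labelled MYC and Zab are closer in ADAR, with a log2 difference of -0.25, against 2.77 for MYC. In MYC over Zab the median log2 difference of the 60 canonical targets was 0.324, with 37 higher and 5 lower (adjusted p = 2.36e-06 by camera, and adjusted p = 0.0219 with an estimated correlation). For these targets, this argues against the ADAR difference as the whole cause. The Zab libraries differ from the MYC ones in coding share as well. Other lists varied in MYC over Zab. As in MYC over WT, ribosome biogenesis was higher (median 0.349) and extracellular matrix lower (-0.757). But histones were lower there (0 of 38 up and 37 down, median -0.841, adjusted p = 7.14e-19 by camera), as was glycolysis and hypoxia (-0.284). By camera p53 targets (adjusted p = 0.665), heat shock (0.51), S phase (0.656) and nucleotide synthesis (0.656) did not pass. Of 29 p53 targets 10 were higher and 9 lower, with a median of 0.033, so their fall in MYC over WT was not seen against Zab.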
